A study of Arabidopsis thaliana with 18 samples.

How the data were processed

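Total RNA of the Arabidopsis thaliana accession Van-0 was labelled with biotin and hybridised to ATH1 arrays, 1 sample per array, per the labels. The deposited table holds 1 intensity per probe set and array for 22810 probe sets on 18 arrays. The submitters' processing notes name MAS5, Affymetrix's algorithm that summarises the probes of a probe set into 1 signal for each array separately. Its version, the scanner and any other step are not given in the sources used here. The deposited intensities were on a linear scale, and the mean of each array without the lowest and the highest 2% of its values was 100, which is the scaling that MAS5 applies. Such scaling sets the overall level of the arrays equal, so a change shared by most transcripts would not be seen. MAS5 treats each array alone and leaves low signals noisy.

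The samples were grouped by the treatment in their descriptions, 9 with 0.02% silwet and 9 with 0.3 mM SA in 0.02% silwet. Each title also gives a Rep number from 1 to 3, and each treatment holds each Rep number on 3 arrays. No label used here says what separates the 3 arrays that share a treatment and a Rep number, so the 9 arrays of a treatment entered the comparison as 1 group. Arrays are named here by treatment and a number from 1 to 9 in the order of their first title number. Runs of 3 consecutive first title numbers hold each Rep number once, and are called title sets here: set 1 holds the arrays numbered 1 to 3 of each treatment, set 2 those numbered 4 to 6 and set 3 those numbered 7 to 9. Silwet and SA arrays of the same number also have adjoining second title numbers, in the sorted order of these arrays (for example 347 and 348, or 312 and 318). No label says what a title set or a second title number marks. No label says that the samples came from separate plants or pots, so the p-values measure the spread between these samples, which may be partly technical. No pair of arrays held identical values: the median absolute log2 difference of a pair was at least 0.23, so all 18 were counted.

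The signals were analysed as log2(signal + 2), the pseudocount being the 10th percentile of all values rounded to a whole number. A fold change on this scale understates the change of low signals. The 64 AFFX control probe sets were left out, and so was the lowest 30% of probe sets by mean over all arrays, which left 15922. No further normalization between arrays was applied. SA was compared with silwet by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Whether the effect differed between Rep numbers was tested by the F-test of their interaction with treatment. The precision is limited by the number of arrays. Simulated data were made in 5 runs with 200 changed probe sets each among 15922. With independent noise, 62.6% of 2-fold and 96.0% of 4-fold changes were recovered. The shares were 63.6% and 95.8% when the within-treatment residuals of these arrays, dealt anew, served as noise. Each of these changes had the same size on all SA arrays. The shares therefore do not apply to a change carried mainly by some SA arrays, such as that of UGT76B1 in the Results.

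Probe sets were named through the platform's annotation table, with symbols updated to the TAIR10.1 gene table by gene identifier. Of the 22810 probe sets, 13513 had 1 gene, 503 had several and 8794 are unnamed here, and 13436 of those with 1 gene matched the gene table. No coordinates were used. The gene lists (18, with 263 members) were fixed before the data were examined, but only 39 members had a probe set naming 1 gene, and 37 of these were tested. For that reason 15 lists of gene families were added by a pattern on the gene symbols, after the annotation was seen and before the treatments were compared. The 31 lists with a tested member were tested by camera with its preset correlation of 0.01, by camera with an estimated correlation and by fry, both on lists of 2 or more members, and by a two-sided exact permutation test over arrays on the mean of the members. Values of all lists were adjusted together. The rule for named genes, also set in advance, took all tested SA-response markers, the 10 largest rises and 10 largest falls among probe sets past the threshold, and from each other list the members past the threshold or, with none, the member with the smallest p. No probe set passed, so the second part was empty. A gene with several probe sets was represented by the one with the highest mean. The genes CYP71B35, UGT76D1, PDF1.2, AT5G52810, SAG101, BSMT1, GAPC2 and XTH20, and others said to be so where they stand, lie outside this rule and were chosen after their values were seen.

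Alternatives set in advance covered the pseudocount, the filter on dim probe sets, quantile normalization, median centring, the Rep number as a fixed and as a random block, eBayes without the trend, array weights, each Rep number alone or left out, each array left out, stricter thresholds and an estimated correlation. Alternatives added after the data were seen were a pseudocount of 16, leaving out silwet 4 and silwet 7, a block of arrays with adjoining title numbers, a block of title sets, and 1 to 5 principal components of the residuals as covariates. The counts of probe sets on which 3 or more SA arrays lay beyond all silwet arrays, the F-test over Rep number, the interaction of treatment with title set and the comparison within each title set, from a limma fit of all 18 arrays, were also added then.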

Results

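Transcript levels of the Arabidopsis thaliana accession Van-0 were measured on 18 ATH1 arrays. The series belongs to a project on expression level polymorphism, which concerns differences in transcript level between accessions and their response to a defence signal. Of the 18 samples, 9 had been treated with 0.02% silwet, an organosilicone surfactant that helps a solution spread over plant surfaces, and 9 with 0.3 mM SA (salicylic acid, a plant hormone of the defence against pathogens) in the same surfactant. The Rep numbers 1, 2 and 3 each stood on 3 arrays of each treatment. All arrays had a trimmed mean signal of 100, and their median signals lay between 23.3 and 36.6.

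The comparison of SA with silwet asks which transcripts respond to the hormone beyond the surfactant. Among the genes taken by the naming rule, the widest difference was that of UGT76B1 (AT3G11340), which encodes a UDP-glycosyltransferase able to conjugate SA. Its mean signal was 521 ± 691 (SD, n = 9) with SA and 65.2 ± 58.9 (SD, n = 9) with silwet, a log2 difference of 1.82 ± 0.85 (SE). The log2 difference was 3.65, 0.51 and 1.32 (SE 0.43 each) in title sets 1, 2 and 3, runs of 3 arrays of each treatment with consecutive title numbers, in a comparison chosen after the values were seen. The highest signals were those of SA 1, SA 2 and SA 3 in set 1 (1561, 1356 and 1398), and no silwet array exceeded 188. GRX480 (AT1G28480), a glutaredoxin induced by SA, had 392 ± 283 with SA and 281 ± 172 with silwet (SD, n = 9). WRKY53 (AT4G23810), a transcription factor of defence and senescence, had 248 ± 237 and 160 ± 65.4. In title sets 1, 2 and 3 the log2 difference was 0.93, 0.20 and -0.19 for GRX480. For WRKY53 it was 1.27, -0.49 and -0.31.

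None of these differences between all 9 SA and all 9 silwet arrays passed the test against the spread between arrays. By limma, 0 of 15922 probe sets passed an adjusted p of 0.05, the smallest adjusted p was 0.431, and 240 probe sets had an unadjusted p under 0.05 (111 higher and 129 lower with SA), against 796 expected by chance. The median log2 difference over all probe sets was -0.02, and 19 probe sets differed at least 2-fold in their means, 16 of them higher with SA. Among named genes outside the naming rule, chosen after their values were seen, AT3G24820 had 15.4 ± 4.69 with SA and 25.3 ± 4.97 with silwet, and AT5G44570 had 582 ± 406 and 185 ± 65.4 (SD, n = 9). Both missed the adjusted threshold of limma, with an adjusted p of 1. This fit takes no account of the title sets and counts differences between them as spread. The sets, taken up after the values were seen, and their interaction with treatment held 46.3% of the variance within treatments. Other assignments of the arrays to 3 sets held 22.6% in the median. If the sets mark conditions, the fit pools those conditions. The 0 calls therefore do not show that SA had no effect. With title sets as a block, added after the data were seen, limma called 1 probe set that is unnamed here, with 498 at an unadjusted p under 0.05.

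**Figure D1:**
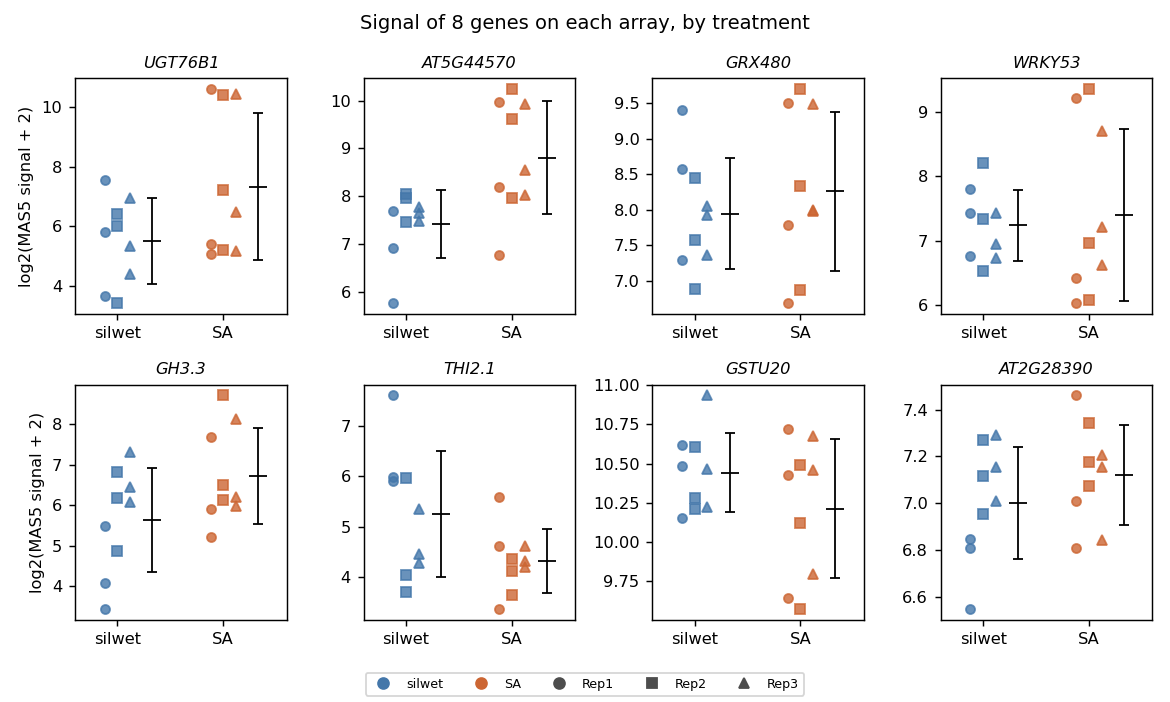
Signals of 8 genes on the 9 silwet and 9 SA arrays, as log2(MAS5 signal + 2), with circles, squares and triangles for Rep numbers 1, 2 and 3; the bar and whiskers give the mean and SD over 9 arrays. For UGT76B1, 3 SA arrays lie at signals of 1356 to 1561 and the other SA arrays overlap the silwet arrays, and AT5G44570 was chosen for the plot after its values were seen.

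The SA lists did not pass their tests. Of the SA-response markers set in advance, only GRX480 and WRKY53 could be tested. The others, among them PR1, BGL2, PR5 and WRKY70, had no probe set naming 1 gene here, so nothing can be said about them. Both tested markers had a higher mean with SA over the 9 arrays, though not in each title set. The adjusted p of this list was 0.71 by camera. Of the 4 tested genes of SA synthesis, perception and conversion, 3 were higher and 1, BSMT1, was lower, with a log2 difference of -0.0078 that turned positive under median centring. Besides UGT76B1 these were AT5G52810, a reductase gene of N-hydroxypipecolic acid synthesis (261 ± 181 with SA, 171 ± 47.0 with silwet), SAG101 (40.6 ± 21.6 and 35.9 ± 12.3) and the methyltransferase gene BSMT1 (43.3 ± 29.1 and 55.5 ± 45.1; all SD, n = 9). This list had an adjusted p of 0.205 by camera and 0.798 with an estimated correlation. Its other members set in advance, among them ICS1, EDS1, PAD4 and NPR1, were not tested. No member of any list passed when adjusted over the list alone.

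Of the 31 lists, 3 passed camera with the preset correlation, and none of them passed with an estimated correlation, by fry or by the exact permutation test. Cytochrome P450 enzymes, a family of oxygenases, were lower with SA in 13 of 15 tested members, with a mean log2 difference of -0.27 (adjusted p = 0.00589 by camera and adjusted p = 0.423 with an estimated correlation). Of the tested members, the one with the smallest p was CYP71B24 (AT3G26230), at 20.6 ± 6.94 with SA and 32.1 ± 11.7 with silwet, and CYP71B35 had 33.2 ± 16.6 and 44.2 ± 12.6 (SD, n = 9). Most of the tested P450 genes belong to the CYP71B group of near relatives, whose probe sets can share signal. UDP-glycosyltransferases, which attach sugars to small molecules, were higher in 22 of 31 tested members, with a mean log2 difference of 0.16 (adjusted p = 0.0217 by camera and adjusted p = 0.224 with an estimated correlation). The list includes UGT76B1, at a log2 difference of 1.82, and the median over its members was 0.14. Other examples were UGT84A4 (31.1 ± 7.06 and 23.2 ± 8.12) and UGT76D1 (13.7 ± 3.88 and 9.95 ± 3.43). The jasmonate and ethylene defence list rested on 2 genes, THI2.1 (AT1G72260), a thionin gene, with 19.7 ± 10.9 and 52.9 ± 56.9, and PDF1.2 (AT5G44420), a defensin gene, with 19.8 ± 15.2 and 42.8 ± 57.4 (SD, n = 9); its mean log2 difference was -0.84 (adjusted p = 0.0306 by camera and adjusted p = 0.224 with an estimated correlation).

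The calls ended under several alternatives, by the adjusted p of camera, with and without a smaller shift. The P450 call ended without replicate 3 (mean log2 difference -0.20, adjusted p 0.114), with the lowest 50% left out (-0.29, 0.0511) and in Rep number 1 alone (-0.12, 0.592), and over its alternatives the adjusted p ran from 0.000403 to 0.592. The glycosyltransferase shift kept about its size, 0.15 to 0.17, where the call ended without replicate 3 (0.7), silwet 3 (0.176), silwet 6 (0.0958) or SA 4 (0.065), and was 0.11 without SA 1 (0.0565), 0.07 in Rep number 2 alone (0.419) and 0.22 in Rep number 1 alone (0.61), with a range of adjusted p from 0.000403 to 0.7. The shift of THI2.1 and PDF1.2 stayed between -0.89 and -0.81 where the call ended without silwet 3 (0.0638), SA 5 (0.0538) or SA 8 (0.0722) and after quantile normalization (0.059). It was -0.75 without SA 2 (0.0524), -0.74 without silwet 1 (0.138), -0.63 without silwet 7 (0.0544), -0.44 without silwet 4 and silwet 7 (0.167), -0.35 without replicate 1 (0.427) and -0.29 with array weights (0.693). In Rep numbers 1, 2 and 3 alone it was -1.83 (0.0681), -0.64 (0.185) and -0.06 (0.961), with a range of adjusted p from 0.0096 to 0.961.

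**Figure D2:**
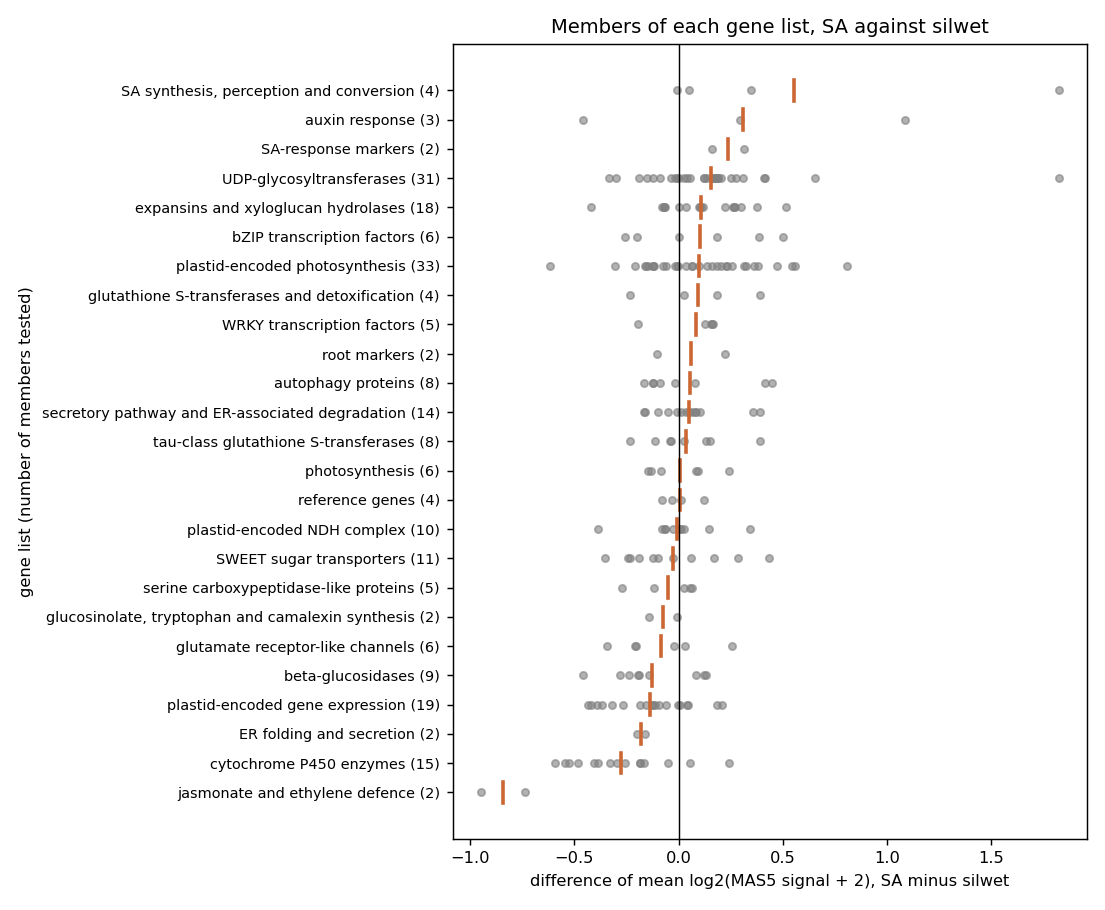
Difference of the mean log2(MAS5 signal + 2) between the SA and silwet arrays (9 each) for each member (grey points) of the lists with 2 or more tested members, and the mean over members (orange bars). The means of the 25 lists lie between -0.84 and 0.55, and the point at 1.82 in 2 lists is UGT76B1.

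Of 6 nuclear photosynthesis genes, 3 were higher and 3 lower (4 and 2 after quantile normalization), with a mean log2 difference of 0.01 (adjusted p = 0.986 by camera). Rubisco activase (RCA) had a signal of 3185 ± 581 with SA and 2783 ± 811 with silwet. Its lower silwet mean rests on silwet 4 and silwet 7 (1429 and 1497), with the other silwet arrays at 2648 to 3755. The auxin list had 2 of 3 members higher (adjusted p = 0.71 by camera), among them GH3.3, which encodes an auxin-conjugating enzyme (143 ± 132 and 64.7 ± 48.3). Its lowest silwet signals were also those of silwet 4 and silwet 7 (14.9 and 8.74). Of the 4 detoxification genes, 3 were higher (adjusted p = 0.986 by camera), and GSTU20, an abundant glutathione S-transferase transcript, had 1232 ± 355 and 1409 ± 262. Both tested genes of ER folding had negative log2 differences (adjusted p = 0.71 by camera), with BZIP60 at 673 ± 374 and 728 ± 340. Plastid-encoded genes of photosynthesis were higher in 19 of 33 members (22 after quantile normalization; adjusted p = 0.531 by camera), with psbE at 1190 ± 338 and 878 ± 429, while plastid-encoded genes of gene expression were lower in 14 of 19 (13 after median centring; adjusted p = 0.0782 by camera), with rpoA at 648 ± 158 and 879 ± 280 (all SD, n = 9). Expansins and xyloglucan hydrolases were higher in 13 of 18 members (12 after quantile normalization; adjusted p = 0.157 by camera), with log2 differences of 0.52 for XTH29 and -0.42 for XTH20.

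The remaining lists of 2 or more tested members, among them WRKY and bZIP factors, beta-glucosidases, SWEET sugar transporters, secretory pathway, autophagy, glutamate receptor-like, serine carboxypeptidase-like, tau-class glutathione S-transferase, plastid NDH complex and glucosinolate genes, had adjusted p between 0.445 and 0.963 by camera. The mean and the median log2 difference had opposite signs in the autophagy, serine carboxypeptidase-like, tau-class and reference gene lists. Lists with 1 tested member were described by that member, with log2 differences of 0.65 for SAG29 (senescence), 0.23 for the clock gene GI, 0.17 for STZ (touch response), 0.34 for ATHSP22.0 (heat shock) and -0.07 for the expansin gene EXPA8, whose mean signal was 468 ± 271 with SA and 430 ± 188 with silwet (SD, n = 9). The adjusted p of these lists lay between 0.603 and 0.963 by camera. GI was lowest on silwet 4 and silwet 7 (56.6 and 68.6), with the other silwet arrays at 121.7 to 490.1. Its positive difference rests on these arrays with low signal. The root marker EXPA18 had 16.8 ± 4.45 and 14.1 ± 3.56, and the guard cell marker FMA had 42.5 ± 11.2 and 43.0 ± 10.1, with adjusted p of 0.71 and 0.963 for their lists by camera. The lists of receptor-like kinases and of flower markers had no tested member. The 4 reference genes had a mean log2 difference of 0.01 (adjusted p = 0.963 by camera), with GAPC2 at 2684 ± 458 and 2826 ± 385.

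The ratio of 5' to 3' signal of control transcripts, which falls when RNA is degraded or labelled fragments are short, was lowest on silwet 7 and silwet 4. For GAPDH it was 0.225 and 0.465 on these arrays, with means of 1.01 ± 0.17 with SA and 0.90 ± 0.34 with silwet (SD, n = 9; exact permutation p = 0.415, adjusted p = 0.799). The same arrays held high signals of THI2.1 (silwet 4, 194) and rpoA (silwet 7, 1522). They also held the lowest silwet signals of RCA (1429 on silwet 4 and 1497 on silwet 7) and GI (56.6 and 68.6). The same was so for GH3.3 (14.9 and 8.74), AT5G44570 (118.7 and 52.9), BZIP28, SEC10 and WRKY20. RCA, GI and these genes all had positive log2 differences. Without both arrays, limma called 0 probe sets, with 155 at an unadjusted p under 0.05, and camera called 5 lists.

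The interaction of treatment with Rep number asks whether the effect of SA differed between the repeats that these numbers may mark. By limma, 0 of 15922 probe sets passed, the smallest adjusted p was 0.911, and 631 had an unadjusted p under 0.05, against 796 expected by chance. For the SA-converting gene UGT76B1, each Rep number held 1 SA array with a signal of 1356 or more, and the other SA arrays lay between 31.9 and 146. Without silwet 1, 62 probe sets passed the interaction test.

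Most of the variance between arrays followed neither label. The first principal component held 38.5% of it and had UGT76B1, the ubiquitin ligase genes PUB22 and PUB23 and the syntaxin-binding gene KEU among the named genes at one end and SAG29 and BZIP61 at the other; these genes were chosen after their values were seen. Treatment held 3.7% of the total variance (exact permutation p = 0.74; 5.88% expected by chance) and Rep number 16.8% (exact permutation p = 0.126; 11.8% expected by chance), with adjusted p of 0.74 and 0.252. PUB23 had signals of 82.8, 288 and 263 on silwet 1, silwet 2 and silwet 3. On SA 1, SA 2 and SA 3 its signals were 323, 259 and 233, and on the other arrays 13.6 to 61.9. The highest scores on the first component were those of silwet 2, silwet 3, SA 1, SA 2 and SA 3 (46.5 to 69.8). These are arrays of title set 1 from both treatments, while silwet 1 of that set scored -37.3.

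**Figure D3:**
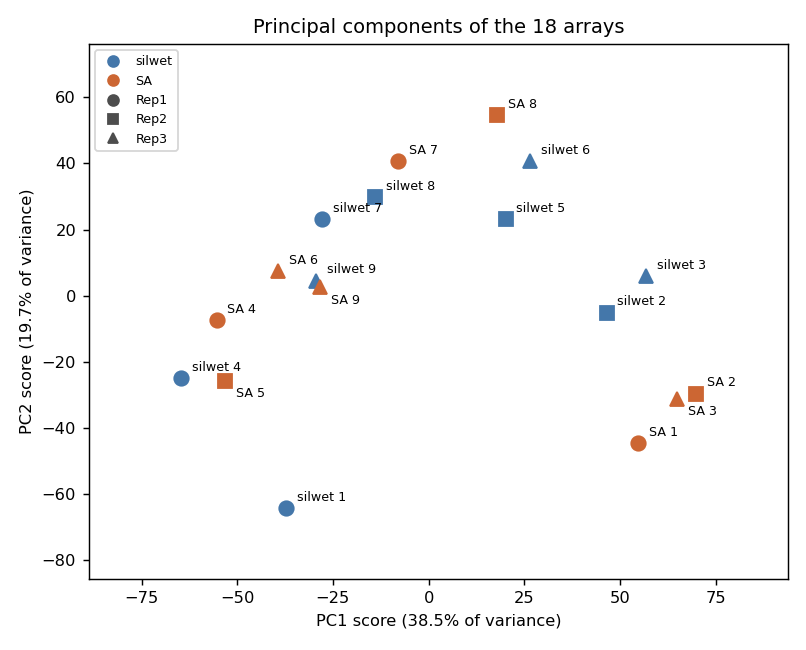
Scores of the 18 arrays on the first and second principal components of the log2 signals of 15922 probe sets, with 38.5% and 19.7% of the variance; colours give the treatment and symbols the Rep number. Silwet and SA arrays are mixed along both axes, and SA 1, SA 2 and SA 3 lie at PC1 scores of 54.7, 69.8 and 64.9. Silwet 1, silwet 2 and silwet 3 lie at -37.3, 46.5 and 56.8.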

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

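The tests of Rep number as a batch, of the splits for SA arrays lying beyond all silwet arrays, and of the splits for the treatment count, the interaction, the residual components and the title sets were chosen after the results were seen. Of 124 groups of 9 arrays looked at, 8 held an array set apart from the rest by more than Dixon's 95% critical ratio, and chance gives 6.2 if values are normally distributed. Single genes were looked at here as linear signals, which need not be normal, and lists as mean log2 signals. Whether the genes below would stand apart on the log2 scale used elsewhere was not tested.

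THI2.1, a thionin gene of the jasmonate response, stood at 194 on silwet 4, with 10.9 to 61.4 on the other silwet arrays, and at 45.8 on SA 4, with 8.24 to 22.5 on the other SA arrays. GRX480, a glutaredoxin gene induced by SA, stood at 675 on silwet 1, with 116 to 377 on the others. The carboxypeptidase-like gene SCPL34 stood at 144 on silwet 9, with 60.6 to 99.1 on the others. The plastid polymerase gene rpoA stood at 1520 on silwet 7, with 577 to 1000 on the others. The mean log2 signal of the cytochrome P450 genes was 4.96 on silwet 1, with 5.56 to 5.93 on the others. The mean log2 signal of the plastid NDH genes was 9.28 on silwet 9, with 7.83 to 8.44 on the other silwet arrays, and 7.68 on SA 7, with 8.08 to 8.41 on the other SA arrays.

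Arrays that share a treatment and a Rep number differed widely in genes such as PUB22, PUB23 and KEU, and 38.5% of the variance lay on 1 component. Scaling as the whole cause is argued against by a share of 37.3% after quantile normalization. The low 5' signal of silwet 4 and silwet 7 is argued against as the whole cause by a share of 41.9% without them. These arrays had the highest scores on the third component (49.7 and 70.5), so this share does not test whether it was a part of the cause. Rep number as a batch held 16.8% of the total variance. It is the same on arrays that share a treatment and a Rep number, so it cannot make them differ, whatever its share. The title sets and their interaction with treatment held 46.3% of the variance within treatments. Of 100 assignments of the arrays to sets, 1, the real one, held as much (median of the others 22.6%, highest other 42.9%). But the sets were taken up after SA 1, SA 2 and SA 3 were seen to stand apart, so chance stays open. The share missed the 50% set for the whole cause. Whether a set marks a technical or a biological difference cannot be told apart because the labels do not say.

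UGT76B1, AT5G44570, UGT73D1 and AT1G02360 were among 27 probe sets on which 3 or more SA arrays lay over 2-fold above every silwet array, against 0 in the reverse comparison, while 9 had 3 or more SA arrays so far below every silwet array, against 10 in reverse; the 27 and 9 were 19 and 0 at a pseudocount of 16, 162 and 140 at a margin of 0.5 (log2), 49 and 65 with 2 arrays required in place of 3, and 3 and 1 with 4 arrays required. SA 1, SA 2 and SA 3, the SA arrays of title set 1, each counted in 26 of them, and 4 probe sets met the condition without any one of these arrays, 52 without silwet 3, and 9, 0 and 3 without replicates 1, 2 and 3, while the 9 below were 2 without SA 1, SA 2 or SA 3, 20 without silwet 3, 15 without silwet 2, 14 without silwet 1 or silwet 9, and 3, 1 and 0 without replicates 1, 2 and 3. Of the 27, 23 met the condition on SA 1, SA 2 and SA 3 alone, as did 7 of the 9 below. The rule needs 3 arrays, so these fall away when 1 of the 3 is left out or 4 are required. Each replicate also holds 1 of the 3. Such falls do not measure stability. Scaling is argued against by 24 of the 27 that met the condition after quantile normalization. Chance could not be excluded: 15 of 100 free splits of the arrays gave as many (highest other 217, which points to a structure of the samples), and of splits drawn within title sets 5 of 100 did (highest other 28), which is at the bound of 5. A split within title sets can keep SA 1, SA 2 and SA 3 together against silwet 1, silwet 2 and silwet 3. Such a split holds the pattern itself, so the share of these splits does not decide about chance. A response to SA, in title set 1 or in others as well, stays open (the comparison within sets is among the other observations).

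For the lists, with the P450 and glycosyltransferase genes among them, chance could not be excluded: 25 of 100 splits gave 3 or more, and the highest other gave 10. Every split reaches a count of 0, so the 100 of 100 splits for the count of probe sets (0 by limma, 240 at an unadjusted p under 0.05, highest other 0) and for the interaction with Rep number (0 by limma, 631 at an unadjusted p under 0.05, highest other 2042) say nothing about chance.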

How the results depend on the processing

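The pseudocount of 16, the fits without silwet 4 and silwet 7, with residual components, title-number pairs and title sets, and all alternatives of the Rep number test were chosen after the data were seen. The count of probe sets was 0 by limma under all 38 alternatives without residual components, title pairs or title sets, with 110 to 1090 at an unadjusted p under 0.05. With 2, 3, 4 and 5 residual components it was 2, 243, 489 and 746. These components were taken from the residuals of the treatment fit. They therefore leave the log2 differences unchanged and lower only the residual spread, so the count can rise without any larger difference. Chance could not be excluded: 45, 60, 62 and 62 of 100 splits gave as many. The other splits had a median of 0, 452, 733 and 1042. The highest other gave 5368, 6644, 6995 and 7307, which points to a structure of the samples. With the Rep number as a fixed block the count was 0 by limma (smallest adjusted p 0.958), as a random block 0 (285 at an unadjusted p under 0.05), with title-number pairs as a block 0 (766 at an unadjusted p under 0.05), and with title sets as a block 1 (498 at an unadjusted p under 0.05), the cause was not tested. As pairs, neither number met the bound of r over 0.1 in every pair: it held in 12 of 27 pairs that share a Rep number (mean r 0.076, other pairs -0.037; 12 of 18 arrays had their best partner there) and in 6 of 9 title pairs (mean r 0.32, other pairs -0.04; 10 of 18 arrays had their best partner there). Pairs of a silwet and an SA array from the same title set had a mean r of 0.17, and those from different sets -0.084. The 9 title pairs are among the pairs that share a Rep number and among those of the same title set. These means are therefore not separate signs of a pairing. Missing the bound in some pairs does not rule out a pairing by title number, which the main fit leaves out. Camera was not run with the random block, which it cannot take.

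The count of lists, 3, was 1 with the lowest 50% left out, 0 with Rep number 1 alone, 7 with Rep number 2 alone, 5 with Rep number 3 alone, 1 at an adjusted p under 0.01, 0 with an estimated correlation and 5 without silwet 4 and silwet 7. It ran from 1 to 4 without a replicate and from 1 to 6 without an array (silwet 3, 1; silwet 4, 5; silwet 9, 5; SA 3, 6). The cause was not tested. Cytochrome P450 enzymes passed in 35 of 39 alternatives, UDP-glycosyltransferases in 30 of 39 and THI2.1 with PDF1.2 in 23 of 38, each with its direction kept in all of them; the last list had no tested member with the lowest 50% left out. The interaction count was 0 in 31 of 32 alternatives (at most 1135 at an unadjusted p under 0.05 over all 32) and 62 without silwet 1, the cause was not tested.

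Of 31 named genes, 14, counting each probe set once, kept the sign of their difference under all alternatives. Low signals are the least certain: 10.4% to 13.1% of the values on each array lay below the pseudocount.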

Other observations

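The F-test over Rep number was chosen after the data were seen, and the predictions for its splits were written before they were run. By limma, 4 of 15922 probe sets differed between Rep numbers with treatment in the model. An unadjusted p under 0.05 was reached by 2531, against 796 expected by chance. The plastid gene psbA, which encodes the D1 protein of photosystem II, had mean log2 signals of 10.78 ± 0.35, 8.41 ± 0.57 and 6.82 ± 1.22 (SD, n = 6) in Rep numbers 1, 2 and 3, with a limma adjusted p of 0.00123. The others were AT3G12150, AT1G47970 and a probe set that is unnamed here. Of 62 plastid-encoded genes, 23 passed when adjusted over the plastid lists, among them ndhD, petN, rps2, rpoC1 and rbcL, and the direction differed between genes: of 30 with an unadjusted p under 0.05, 11 were highest in Rep number 1.

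For the plastid-encoded genes chance is argued against by the splits of the arrays into 6, 6 and 6, though the test was chosen after the data were seen: 1 of 100, the real one, gave 23 (highest other 6). For the 4 probe sets, 3 of 100 splits gave as many, but the highest other gave 2458, which points to a structure of the samples, and Rep number held no larger share of the variance than chance allows (exact permutation p = 0.126), so that count is not taken as established. The counts rested on some arrays. Without silwet 4 and silwet 7, both of Rep number 1 and with low 5' signal, 1 probe set and 5 plastid-encoded genes passed, without replicate 1 both counts were 0, without replicate 2 they were 2 and 27, and without replicate 3 they were 1 and 7. The count of 4 probe sets was 152 without SA 5, 151 without SA 7, 38 without silwet 1, 9 without SA 1, 2 without silwet 6, and 1 without silwet 3, silwet 4, silwet 7, SA 4 or SA 9. The 23 plastid-encoded genes were 13 without silwet 3, 9 without silwet 4, 13 without silwet 6, 11 without silwet 7 and 13 without SA 4, and 14 after median centring. Whether Rep number marks a day, a batch of plants or a batch of arrays is not in the labels.

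The comparison within title sets was chosen after the values of SA 1, SA 2 and SA 3 were seen, so it is a hypothesis and no independent evidence. UGT76B1, which encodes an SA-conjugating enzyme, differed between SA and silwet by a log2 of 3.65 ± 0.43 (SE, n = 3) in set 1, with a limma adjusted p of 0.000979, by 0.51 ± 0.43 in set 2 (0.632) and by 1.32 ± 0.43 in set 3 (0.991), where each SA array lay above each silwet array. SCPL34 (-1.62 ± 0.30; 0.53 and 0.27 in sets 2 and 3) and BGLU44 (-0.86 ± 0.14; 0.10 and -0.07) also passed in set 1, while the SA-response marker WRKY53 (1.27 ± 0.32, limma adjusted p 0.0727; -0.49 and -0.31 in sets 2 and 3) and GRX480 (0.93 ± 0.40, 0.34; 0.20 and -0.19) did not, and none of them passed in set 2 or 3. By limma, 132 probe sets passed in set 1 (74 higher and 58 lower; 53 and 16 after median centring, 94 and 73 after quantile normalization, 114 and 45 at a pseudocount of 16, 7 and 0 with array weights), 0 in set 2 (1710 at an unadjusted p under 0.05) and 0 in set 3 (308). Each set allows 10 splits into 3 and 3, too few for a share under 0.05: in set 1 the real split gave 132 and the highest other 1 (1 of 10 as large), and in sets 2 and 3 all 10 reach the count of 0.

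Whether the effect differs between sets was tested by the interaction, which 27 probe sets passed by limma (1964 at an unadjusted p under 0.05). Chance could not be excluded: 9 of 100 assignments of the arrays to sets gave as many, and the highest other gave 2572, which points to a structure of the samples. An assignment can also keep SA 1, SA 2 and SA 3 in the same set, so these assignments do not decide about chance. UGT76B1 missed the threshold of the interaction (limma adjusted p 0.0663). Over 32 alternatives the interaction count ran from 0 to 427, the count in set 1 from 1 to 324, in set 2 from 0 to 2000 (array weights; 589 without replicate 1) and in set 3 stayed 0. The count in set 1 was 1 without replicate 2 or 3, 19 without replicate 1, 13 without SA 1 or SA 2, 28 without SA 3, 84 without SA 6, 64 without silwet 1, 14 without silwet 2 and 230 without silwet 4. The interaction count was 5 without silwet 1, silwet 5, SA 2, SA 4 or SA 6, 4 without silwet 6, 6 without SA 1, 11 without SA 3, 12 without silwet 2, 93 without silwet 3 and 332 without silwet 4.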
